A study of Mus musculus with 6 samples.

How the data were processed

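RNA from the neck region of the stomach corpus, taken by laser capture microdissection of unfixed frozen sections, was sequenced in 3 wild-type and 3 Cldn18 knockout libraries. Groups and replicate numbers were taken from the sample labels. The number of sections or animals behind a library is not given in the sources used here.

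Per the submitters' processing notes the authors used STAR, featureCounts and DESeq with the mm10 genome; their roles, versions and annotation are not given in the sources used here, and neither is the strandedness, so genes overlapping on opposite strands cannot be told apart. The authors deposited a table of normalized counts, a signal that is never negative, for 38720 rows. The values of each library were whole multiples of 1 number, within 0.05 reads for 100% of values, and that number equalled the inverse of a DESeq2 size factor computed on the recovered reads. The deposited table of the authors' own comparison lists 23086 genes with means, a fold change (a ratio) and p-values with an adjusted p. It was used only as an alternative and lists no symbols of the form Gm and digits. A total of 27 rows hold a date in place of a symbol. Symbols were matched to GENCODE vM21 for 92.0% of rows to give biotypes and coordinates in mm10.

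The main test was limma 3.58.1 (lmFit and eBayes with a mean trend, R 4.3.3) on log2(normalized count + 1), two-sided, with Benjamini-Hochberg adjustment over 17432 genes with a value of at least 10 in at least 3 of the 6 libraries. A gene was called at adjusted p under 0.05. Fold changes are on that log2 scale, which understates the change of low genes. Before the data were examined, 51 gene lists were fixed, and each was tested with camera at a preset correlation of 0.01 and Benjamini-Hochberg adjustment over the lists. Counts of list members cover only those that passed the filter on values, which a gene can do on the 3 libraries of 1 group alone. No list call held with an estimated correlation. The named genes followed a rule fixed at the same time: Cldn18, the 12 largest increases and 12 largest decreases among called genes with groups that do not overlap and a mean of at least 100 in the higher group, up to 4 called members of each list, and a fixed set of markers. Genes of the third kind were left out in places to keep the text readable, and 1 result under the rule is not reported here.

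The procedure was tested on simulated data. In 20 simulated datasets of this comparison, each with 200 changed genes among 16967 tested on average, the test found 4.8% of genes changed 1.5-fold, 43.5% at 2-fold, 85.9% at 4-fold and 97% at 8-fold. The changed genes were drawn only from genes above a minimum mean count, so the shares found do not cover the lowest genes tested. On average 6.77% of calls fell on unchanged genes (2.61% to 10.9% per dataset), somewhat above the nominal level. The real comparison called 44.7% of tested genes, a far larger share than was changed here. Its adjusted p cutoff then admits larger p-values, so these rates need not hold for it. A first version with 1 dataset and dispersions estimated without the size factors exceeded the limit of 10% set for this share. It was replaced by the average of 20 datasets with the limit kept. Raised lists were called in 60 of 60 cases and unchanged lists in 1 of 1000. Genes were simulated independently of one another, so these list figures do not hold for lists of correlated genes.

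Alternatives changed the pseudocount, the filter, the scaling, the variance model, the libraries used and the test, with edgeR 4.0.16 and DESeq2 1.42.0 run on the recovered reads. edgeR with TMM called 8047 genes, of which 7588 were also called by limma. For pseudogenes, blastn 2.17.0 gave the best protein-coding match at a length of at least 150 and an identity of at least 85%. Ratios that rest on up to 3 reads carry a 95% counting interval, which covers counting error only.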

Results

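Claudin 18 is a tight junction protein of the stomach epithelium. The study compared the gastric corpus of wild-type mice with that of mice lacking Cldn18. In both groups the neck region of the gland was cut from frozen sections by laser capture microdissection, and its RNA was sequenced. There were 3 wild-type and 3 Cldn18 knockout libraries, all of the B6:129S5 strain. The sample labels give the age as 7 weeks and the series design text as 7 days, so the age is left open here. Nothing in the labels says that the libraries of a group came from separate animals, and p-values then measure only the spread between these samples, which may be technical.

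The libraries held 37673283 to 52842813 reads on genes. A single locus, Gm26924, took 38.6% to 45.4% of them. Transcripts of the mitochondrial genome took 3.78% ± 0.50 (SD, n = 3) of reads in wild-type and 1.39% ± 0.15 (SD, n = 3) in the knockout (two-sided exact permutation p = 0.1, the smallest that 3 against 3 allows). Processed pseudogenes took 0.149%, 1.10% and 0.549% of reads in wild-type replicates 1, 2 and 3, against 0.110% to 0.126% in the knockout libraries.

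**Figure D1:**
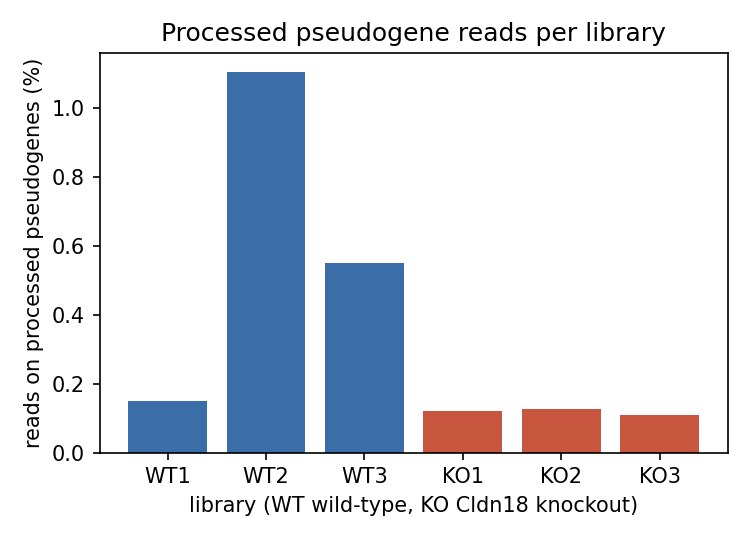
Percent of reads on processed pseudogenes (y axis, from 0) in each of the 6 libraries (x axis), 1 bar per library, with no error bars. Wild-type replicates 2 and 3 stand at 1.10% and 0.549%, and the knockout libraries lie between 0.110% and 0.126%.

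The targeted gene was lower in each knockout library than in each wild-type library, and it was still read. Cldn18 (ENSMUSG00000032473.13, chromosome 9, 99689461 to 99717267, minus strand, mm10) had 30498, 21210 and 23241 normalized counts in wild-type and 13035, 16798 and 15818 in the knockout. Its log2 difference was -0.71 ± 0.20 (SE; limma adjusted p = 0.0134), so the knockout kept 61.3% of the wild-type level. The call was lost without Cldn18 knockout replicate 1 (adjusted p = 0.0882). The counts cover the whole gene, and the deleted part is not given in the sources used here, so they check only the direction of the labels.

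Most members of the parietal cell, chief cell and respiratory chain lists were lower in the knockout. Most members of the cell cycle, gastric (SPEM) metaplasia marker, EGF receptor ligand and feedback, and cholesterol synthesis lists were higher. Of 17432 genes tested, 4053 were higher and 3743 lower in the knockout (limma, adjusted p under 0.05), and 1957 and 2624 of these changed by at least 2-fold. The 3 knockout values lay wholly above or below the 3 wild-type values for 55.2% of genes, against 10% by chance. Without wild-type libraries 2 and 3, a choice made after seeing the data, 3191 genes were higher and 2500 lower. That fit holds a single wild-type library, which is assumed to vary like the knockout libraries. Of the 3743 lower genes, 744 stood at least 3 times higher in wild-type library 2 and at least 1.5 times higher in library 3 than in library 1, and 620 of the lower genes were processed pseudogenes.

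Parietal cell genes fell. Of 25 measured, 18 were lower, 1 (Sh3gl2) was higher and 6 were not called, with the same counts adjusted over the list alone. Both subunits of the gastric proton pump fell: Atp4a went from 276926 ± 34811 to 2829 ± 2119 normalized counts (SD, n = 3; log2 difference -6.88 ± 0.43 SE, adjusted p = 1.37e-06) and Atp4b from 153393 ± 21626 to 1473 ± 931 (log2 difference -6.87 ± 0.35 SE). The potassium channel gene Kcnj16 fell by 7.99 and the anion transporter gene Slc26a7 fell by 6.93 on the log2 scale. The transcription factor gene Esrrg was lower by a log2 difference of -3.62 ± 0.21 (SE). The list was called by camera (adjusted p = 1.22e-09) and lost with an estimated correlation (adjusted p = 0.44).

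Chief cell genes fell as well. Of 16 measured, 10 were lower, 1 (Pdia5) was higher and 5 were not called; adjusted over the list alone, 10 were lower and 2 higher. Chia, an acidic chitinase, had the largest decrease of the named genes on the log2(normalized count + 1) scale, from 142513 ± 71557 to 10.1 ± 6.6 normalized counts (SD, n = 3; log2 difference -13.72 ± 0.44 SE, adjusted p = 3.87e-08). Pgc, which encodes a pepsinogen, fell by 5.31 and Gif, which encodes intrinsic factor, fell by 3.94 on the log2 scale. Clps, which encodes colipase, fell by 9.49 and Pla2g1b, a phospholipase gene outside the list, fell by 9.87. The chief cell list's camera call (adjusted p = 0.00148) was lost with an estimated correlation (adjusted p = 0.46). Of 9 pancreatic acinar genes measured, 5 were lower, 2 higher and 2 not called. That list was not called by camera (adjusted p = 0.18).

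Mucous neck cell genes moved both ways. Of 10 measured, 5 were higher, 4 lower and 1 not called, with the same counts adjusted over the list alone, and the list was not called (adjusted p = 0.48). Gkn3 rose by 2.69 ± 0.25 and Dmbt1 by 3.63 ± 0.18 (log2 difference ± SE), while the gland mucin gene Muc6 fell by 1.71 on the log2 scale. Tff2 was at 50797 ± 11870 in wild-type and 88307 ± 41907 in the knockout (SD, n = 3) and was not called (adjusted p = 0.136). Surface and pit cell genes also went both ways, with 7 higher, 6 lower and 6 not called of 19, the same over the list alone, and no call for the list (adjusted p = 0.99); its median log2 difference was 0.18 and its mean -0.059, with camera's direction up. Krt20 rose by 4.74 ± 0.38 and Psca fell by 2.84 on the log2 scale. Gkn1 was lower (log2 difference -1.62 ± 0.44 SE, adjusted p = 0.0127), a call lost without Cldn18 knockout replicate 1 (adjusted p = 0.0582), without replicate 2 (adjusted p = 0.0956) and after quantile normalization (adjusted p = 0.102). The surface mucin gene Muc5ac (log2 difference -0.62 ± 0.39 SE) and Tff1 (0.21 ± 0.34 SE) were not called.

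**Figure D2:**
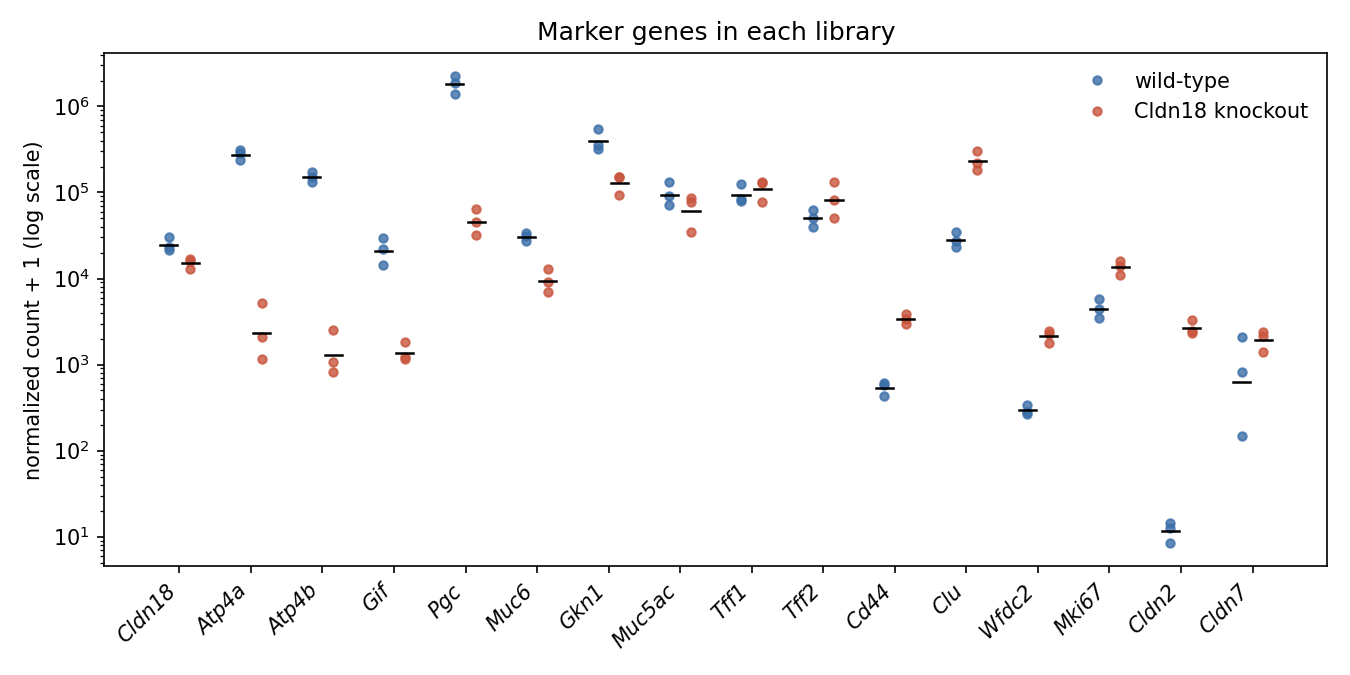
Normalized count plus 1 on a log axis (y axis) for 16 genes (x axis), with 1 point per library, 3 wild-type in blue and 3 Cldn18 knockout in red, and bars at the geometric mean of each group. The arithmetic mean of Atp4a falls from 276926 to 2829 and that of Cldn2 rises from 10.8 to 2712, while the points of Muc5ac, Tff1 and Tff2 overlap.

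Markers of spasmolytic polypeptide-expressing metaplasia, a mucous cell state of the injured corpus, rose for the most part. Of 28 measured, 20 were higher, 3 lower and 5 not called, with the same counts adjusted over the list alone. Muc4, a membrane mucin gene, rose from 17.8 ± 6.2 to 3094 ± 567 normalized counts (SD, n = 3). Clu rose by 3.05 ± 0.30, Wfdc2 by 2.86 ± 0.17 and Cd44 by 2.66 ± 0.17 (log2 difference ± SE). The lower members were Sox9, Olfm4 and Xpr1. Tff2 and Muc6, given above with the mucous neck cell genes, were not members of this list. Tff2 was not called (log2 difference 0.71, limma adjusted p = 0.136) and Muc6 was lower. Some members also belong to other lists tested here, among them Mcm3, Slc7a11, Gpx2 and Pigr. The call of Sox9 was lost in the authors' deposited table (log2 difference -1.53, adjusted p = 0.135). Sox9 stood at 4282, 10257 and 4739 in wild-type replicates 1, 2 and 3. The camera call (adjusted p = 6.00e-08) was lost with an estimated correlation (adjusted p = 0.32). Intestinal metaplasia markers gave 2 higher, 2 lower and 8 not called of 12, the same over the list alone, with no call for the list (adjusted p = 0.86; median 0.021, mean -0.12, camera's direction up). Muc2 was at 17.2 ± 6.79 in wild-type and 14.95 ± 6.49 in the knockout (SD, n = 3; adjusted p = 0.82), and Cdx2 lay below the filter, at 0 to 20.4 in the 6 libraries.

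Cell cycle genes rose without exception among the 42 measured, over all genes and adjusted over the list alone, by log2 differences of 0.79 to 2.42. Mcm5, part of the replicative helicase, went from 720 ± 40 to 3487 ± 302 and Mki67, a proliferation marker, from 4551 ± 1221 to 13611 ± 2365 normalized counts (SD, n = 3). The call (adjusted p = 8.57e-20) was lost with an estimated correlation (adjusted p = 0.41). Of 24 replication-dependent histone genes 20 were higher and 2 lower (adjusted p = 0.54 with an estimated correlation). Adjusted over the list alone, 21 were higher and 2 lower. Many of these genes are near-identical copies, and the reads of those are uncertain. Cdkn1a, a cell cycle inhibitor gene, was not called (log2 difference 0.13 ± 0.25 SE), nor was the stem cell gene Lgr5 (-0.53 ± 0.29 SE). Axin2, a Wnt target, was higher (0.85 ± 0.23 SE, adjusted p = 0.0115), a call lost without Cldn18 knockout replicate 3 (adjusted p = 0.0574).

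Genes of the respiratory chain and of mitochondrial fuel use fell together with the share of mitochondrial reads given above. Of 38 respiratory chain genes 36 were lower and none higher, and of 29 genes of the citric acid cycle and fatty acid oxidation 27 were lower and none higher, with the same counts adjusted over each list alone. Ppargc1a, a coactivator of mitochondrial genes, fell by 3.26 and Acadm fell by 2.04 on the log2 scale. Ppargc1a is also a member of the parietal cell list, of which 18 of 25 genes were lower. Both lists lost the camera call with an estimated correlation (adjusted p = 0.54 for each). Cholesterol synthesis genes rose in 21 of 24 cases with none lower, or 23 adjusted over the list alone (adjusted p = 0.41 with an estimated correlation). Fdps rose by 1.72 ± 0.16 (log2 difference ± SE). Cytosolic ribosomal protein genes, which share reads with pseudogenes and are uncertain for that reason, were higher in 29 and lower in 1 of 38, or 30 and 1 adjusted over the list alone (adjusted p = 0.58 with an estimated correlation).

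**Figure D3:**
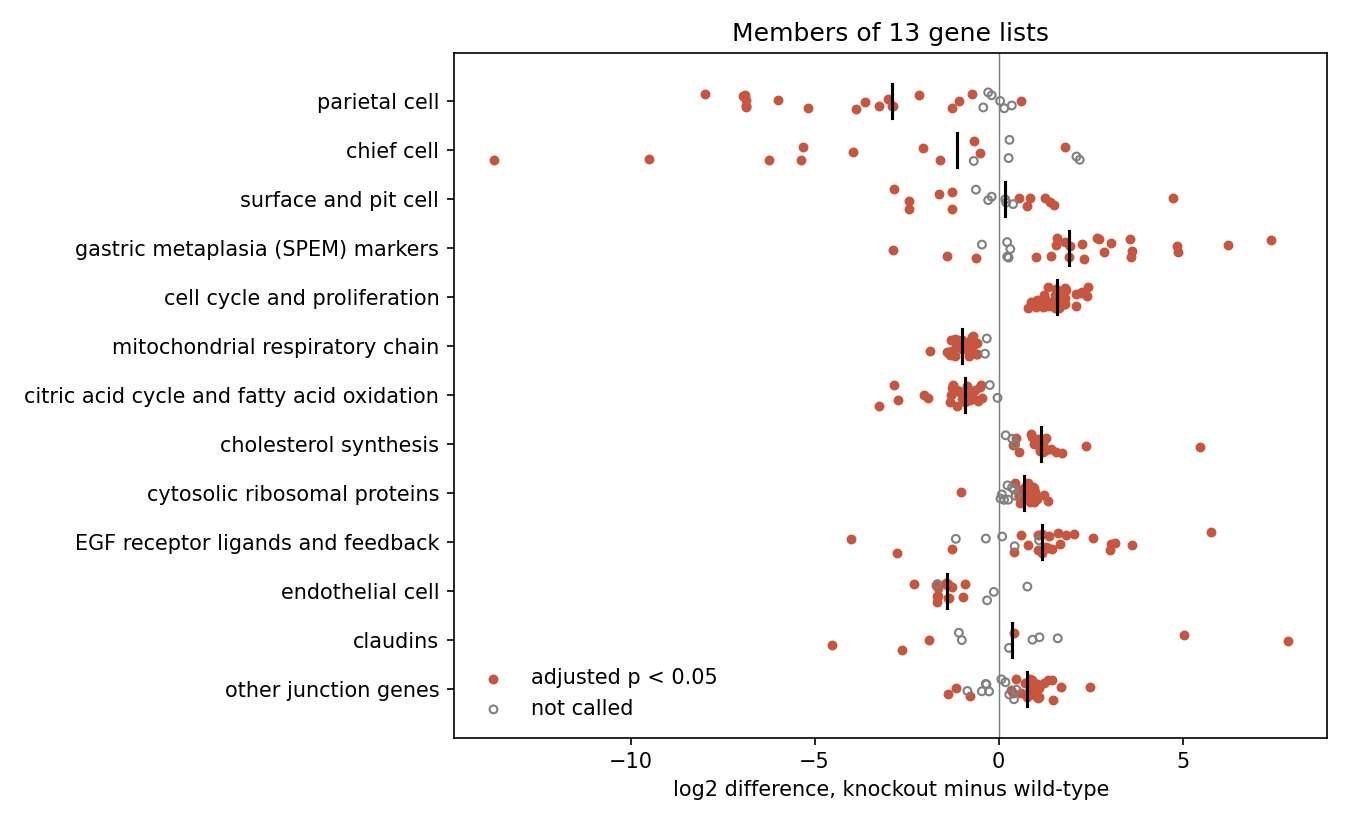
Log2 difference, knockout minus wild-type (x axis), of the members of 13 gene lists (y axis), with 1 point per gene, filled where adjusted p is under 0.05, and a black line at each list's median. Cell cycle members lie between 0.79 and 2.42, and respiratory chain members between -1.88 and -0.32.

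Ligands and feedback genes of the EGF receptor were higher in 21 of 29 cases and lower in 3, against 22 and 3 adjusted over the list alone (adjusted p = 0.35 with an estimated correlation). Areg, which encodes the ligand amphiregulin, went from 67.3 ± 34.7 to 3464 ± 816 normalized counts (SD, n = 3), and Hbegf rose by 3.17 ± 0.24 on the log2 scale. Matrix protease and invasion genes were higher in 18 of 30 and lower in 1, the same over the list alone (adjusted p = 0.54 with an estimated correlation). Mmp10 stood at 4.9, 0 and 4.86 in wild-type and 654, 412 and 1939 in the knockout (log2 difference 7.95 ± 0.75 SE). Simple epithelial keratins were higher in 6 of 6, also over the list alone (adjusted p = 0.46 with an estimated correlation). Among these Krt7 stood at 739, 5625 and 1990 in wild-type replicates 1, 2 and 3.

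The other claudins changed in both directions. Of 12 measured, 3 were higher, 3 lower and 6 not called, with the same counts adjusted over the list alone, and the list was not called (adjusted p = 0.59). Cldn2, which forms a cation channel, went from 10.8 ± 3.1 to 2712 ± 528 normalized counts (SD, n = 3; log2 difference 7.86 ± 0.27 SE, adjusted p = 4.96e-08). Cldn23 rose by 5.05 ± 0.46 and Cldn8 fell by 4.53 on the log2 scale. Cldn7 was not called (adjusted p = 0.094), with 147, 2089 and 819 in wild-type replicates 1, 2 and 3, and 4 of the 12 claudins stood at least 3 times higher in wild-type library 2 and at least 1.5 times higher in library 3 than in library 1. It was called higher without wild-type replicate 2 (adjusted p = 0.00181) and with array weights (adjusted p = 0.0292), and its adjusted p reached 0.457 with DESeq2. Without wild-type libraries 2 and 3 its log2 difference was 3.70, against the single wild-type library with the lowest value. Other junction genes were higher in 24 of 37 and lower in 3, against 25 and 4 adjusted over the list alone (adjusted p = 0.58 with an estimated correlation). Tjp1 (0.84 ± 0.14), Ocln (0.90 ± 0.15) and Cdh1 (1.04 ± 0.22, log2 difference ± SE) were among the higher ones, and Cdh1 lost its call without wild-type libraries 2 and 3 (log2 difference 0.71, adjusted p = 0.0606), where a single wild-type library is left.

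Among the members measured, defence genes were mostly higher and endothelial genes mostly lower. The filter left 22 of 36 listed innate defence genes and 22 of 32 chemokines. It left 10 of 12 class II genes and 13 of 28 T and NK cell genes. S100a8, S100a9, Lcn2, Saa1 and Saa2 were among the innate defence members too low to test. Epithelial innate defence genes were higher in 15 of 22 with none lower, chemokines higher in 14 of 22 and lower in 1, and class II antigen presentation genes higher in 8 of 10, with the same counts adjusted over each list alone (adjusted p = 0.35, 0.46 and 0.54 with an estimated correlation). Pigr, the transporter of secreted antibodies, went from 129 ± 52 to 9176 ± 247 normalized counts (SD, n = 3). Il1b rose by 2.29 ± 0.47 on the log2 scale. None of 13 T and NK cell genes was called by limma, over all genes or adjusted over the list alone, and the list was not called (adjusted p = 0.277). At an unadjusted p under 0.05 there were 2, Cd4 and Cd3g, and edgeR and DESeq2 called 0. Cd4 had the smallest p of that list, with a log2 difference of 1.02 ± 0.41 (SE; adjusted p = 0.0649).

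Of 20 enteroendocrine genes 6 were higher, 2 lower and 12 not called, the same over the list alone, with no call for the list (adjusted p = 0.33). Sst, which encodes somatostatin, fell by 1.64 on the log2 scale. Gast, which encodes gastrin, was at 976, 252 and 13.5 in the 3 knockout libraries and at 0 to 4.94 in wild-type. Endothelial genes were lower in 14 of 18 with none higher, or 15 adjusted over the list alone (adjusted p = 0.55 with an estimated correlation), and Kdr fell by 1.71 on the log2 scale. Erythrocyte genes were lower in 5 of 6 and enteric neuron and glia genes in 6 of 13, the same over each list alone, and smooth muscle genes in 6 of 16, or 5 over the list alone, with none higher in these 3 lists. Fibroblast and matrix genes were higher in 14 of 32 and lower in 3, or 14 and 4 over the list alone. Of these 4 lists the erythrocyte list was called (adjusted p = 0.57 with an estimated correlation), and the others were not (adjusted p = 0.21, 0.22 and 0.11). Stratified squamous genes, markers of the forestomach lining, gave 5 higher, 7 lower and 9 not called of 21, or 5 and 8 adjusted over the list alone, with no call for the list (adjusted p = 0.90). Among these Krt17 stood at 235, 2452 and 799 in wild-type replicates 1, 2 and 3. Of the 21, 7 stood at least 3 times higher in library 2 and at least 1.5 times in library 3 than in library 1. Genes raised in this way made up 5 of the 7 lower squamous genes. They also made up 2 of the 6 lower neuron and glia genes and 2 of the 3 lower fibroblast and matrix genes. Ivl rested on 2 wild-type reads in all, and its knockout to wild-type ratio was 435 (95% counting interval 120 to 3593, counting error only).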

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

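The choices without wild-type libraries 2 and 3, and without the genes raised in both, were made after seeing the data. The first leaves a single wild-type library, which is assumed to vary like the knockout libraries. Over all alternatives the higher genes numbered 1957 to 4650 and the lower genes 2025 to 4504. The count of higher genes moved most with a log2 difference of at least 1 (1957), which by construction drops smaller changes, and that of lower genes in the authors' deposited table (2025), where the cause was not tested. Of 220 called named genes 188 had the same call wherever they were tested, apart from the threshold on size. Not each gene was tested in each alternative: 176 were tested in all 22 with named genes, and 158 of these had the same call in each. Cldn18 stayed lower throughout; its log2 difference of -0.71 misses a threshold of 1, and it ranged from -0.82 to -0.55 with 1 library left out. With an estimated correlation 0 of 24 lists stayed called, against 33 with directional and 50 with mixed fry; fry does not compare a list with other genes. No list test was run on the authors' table, with DESeq2 or with the size threshold. The median of all genes was 0.10 after quantile normalization and -0.15 after upper quartile scaling, against -0.02.

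No pairing by replicate number was seen, but so few libraries cannot exclude one. Same-numbered libraries had correlations of deviations of -0.00366, 0.0214 and -0.173, and no library correlated best with its own number. With the replicate block 3726 genes were higher and 3626 lower, and 25 lists were called. Of the named genes 6 lost their call under the block and 1 gained one. Gkn1 was among those that lost it (limma adjusted p = 0.0804).

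The reversals concern results with no call, and the cause was not tested. With quantile normalization Muc5ac was at 0.017, Muc2 at 0.33, Cdkn1a at -0.024, and the medians of the Notch list at 0.071, enteric neuron and glia at 0.23, stratified squamous at 0.12 and adipocyte at 0.20. With upper quartile scaling Cdkn1a was at -0.011 and list medians were -0.000277 (tuft cell), -0.11 (intestinal metaplasia), -0.0038 (p53 targets), -0.063 (BMP and TGF-beta) and -0.12 (Hedgehog). Without a filter they were -0.038 (tuft cell), -0.23 (intestinal metaplasia), -0.17 (claudins) and -0.44 (neutrophil). With a mean of at least 100 they were 0.29 (Wnt ligands and receptors) and 0.016 (Notch), with TMM 0.028 (Notch), and with array weights -0.11 (intestinal metaplasia), 0.094 (Notch) and 0.019 (smooth muscle). Without wild-type libraries 2 and 3, Tff1 was at -0.22, Cdkn1a at -0.24, and medians at -0.025 (surface and pit), -0.029 (tuft), -0.059 (intestinal metaplasia), 0.011 (Notch), -0.19 (Hedgehog), -0.19 (fibroblast and matrix), 0.10 (pancreatic acinar), 0.032 (stratified squamous) and 0.040 (histone deacetylases). Without the genes raised in those libraries the claudins were at -0.36 and stratified squamous genes at 0.23. With 1 library left out the ranges were -0.52 to 0.077 (Muc2), -0.16 to 0.31 (Cdkn1a), -0.029 to 0.25 (surface and pit), -0.034 to 0.33 (tuft), -0.17 to 0.13 (Notch), -0.024 to 0.25 (BMP and TGF-beta), -0.083 to 0.096 (Hedgehog), -0.33 to 0.000375 (smooth muscle), -1.02 to 0.19 (stratified squamous) and -0.24 to 0.0029 (glycolysis and hypoxia).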

Other observations

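Further gene lists had called members, in a comparison that called 44.7% of all tested genes. Called members alone therefore do not set a list apart. Of 24 oxidative stress genes 14 were higher and 3 lower, or 16 and 3 adjusted over the list alone (adjusted p = 0.60 with an estimated correlation), and Slc7a11, a cystine transporter gene, rose by 4.85 ± 0.33 (log2 difference ± SE). Endoplasmic reticulum and secretory pathway genes were higher in 16 of 28 and lower in 1, the same over the list alone (adjusted p = 0.66 with an estimated correlation). Interferon-stimulated genes were higher in 16 of 49 and lower in 2, or 15 and 2 over the list alone (adjusted p = 0.46 with an estimated correlation), and macrophage genes higher in 12 of 26 and lower in 1, the same over the list alone (adjusted p = 0.58 with an estimated correlation). Wnt target and stem cell genes were higher in 11 of 30 and lower in 5, or 12 and 5 over the list alone (adjusted p = 0.54 with an estimated correlation). Of 46 cytokine and receptor genes listed, 22 passed the filter, and Tnf, Il6 and Ifng were among those that did not. Of the 22, 13 were higher and 2 lower, the same over the list alone (adjusted p = 0.60 with an estimated correlation). Of 18 histone deacetylase genes 8 were lower and 3 higher, the same over the list alone, with no call for the list (adjusted p = 0.27). Lpl, which encodes lipoprotein lipase, fell by 5.46 on the log2 scale. Hamp2, a hepcidin gene, went from 3100 ± 609 to 7.25 ± 3.26 normalized counts (SD, n = 3).

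The tests of pseudogenes and of parietal and chief cell genes below were chosen only after the result was seen. Only 10 splits of the 6 libraries into 3 and 3 exist, too few for a share under 0.05. The real split called 7796 genes and 1 of the 10 splits called as many, the real one, with 0 genes as the highest of the others. For gene lists 2 of the 10 splits called as many as the real 24, and the highest of the others called 25. Every other split mixes wild-type and knockout libraries in both groups. It keeps a part of the genotype difference and spreads the values within each group. The splits therefore decide nothing about chance, for genes or for lists.

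The summed normalized counts of processed pseudogenes were 6.27 times the replicate 1 value in wild-type replicate 2, and 2.66 times in replicate 3. Genomic DNA covers genes by their length, so it would raise silent receptor genes alike. In replicate 2 the receptor genes changed by -0.0842 normalized counts per kb of exon against 133 for the pseudogenes, and their summed ratio to replicate 1 was 0.849. In replicate 3 they gained 0.433 per kb (95% bootstrap interval 0.362 to 0.506) against 42.0 (35.4 to 49.6), with a summed ratio of 1.77. The gains per kb argue against genomic DNA as the whole cause in either replicate, and a small amount in replicate 3 stays open. This measure was chosen after the values were seen, in place of the summed ratio. In replicate 3 that ratio was 1.77 for the receptor genes and 2.66 for the pseudogenes.

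Reads of parent genes counted on their copies would lower the parents. In replicate 2 the parents' median log2 ratio to replicate 1 was -0.00812, against -0.105 for all tested genes. Against other genes of like expression the parents were higher by 0.156 (95% bootstrap interval over genes 0.109 to 0.206), where the gain of the copies needed a difference of -0.121. The needed and the observed change had a rank correlation of -0.271, where this account predicts a positive one. In replicate 3 the parents differed by 0.0506 (0.0189 to 0.0880) from genes of like expression, where -0.0464 was needed, and the rank correlation was -0.143 (-0.240 to -0.0503). With no reference the correlations were -0.290 and -0.206 in replicates 2 and 3. Both changes are computed from the same replicate 1 value of the parent, so its noise pushes these correlations below 0. Their sign therefore decides nothing on its own. Against the median of all genes the parents of replicate 3 stood at -0.0812, below the needed value, but the genes of like expression also had a lower median log2 ratio (-0.267) than all genes (-0.135). The medians against genes of like expression argue against this account as the whole cause in both replicates, while a part of the gain stays open. Earlier forms of this test left the account undecided, in replicate 2 with the parents' own median alone and in replicate 3 with the median of all genes as a reference.

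A candidate explanation is RNA from one other source in these libraries. Among protein-coding genes at least 3 times higher in replicate 2 than in 1, chosen without replicate 3, the median share of the excess in replicate 3 was 0.365. That lies within the middle 50% of the pseudogenes (0.252 to 0.405), but the middle 50% of the protein-coding genes was wider (0.261 to 0.639), so a single common share is not shown for these genes. What such a source would be is open, and no biological explanation was tested.

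Of the parietal and chief cell genes 18 of 25 and 10 of 16 were called lower, with 1 of each called higher, while surface and pit cell members went both ways, with 7 called higher and 6 called lower. A capture that moved toward the mucosal surface would raise these members alike, so the lower ones argue against it as the whole cause, and a part in the change stays open. Fewer chief cells with unchanged expression cannot be told apart from lower expression per cell: Chia and Spdef differed in their fall by 28.3 combined SE, but a member that other cells also express falls less. A genotype effect on the cells themselves stays open, and it was not tested apart from these.

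Sequence of the 129 strain around the targeted allele might add calls near Cldn18. Within 10 Mb 88 of 180 genes were called (48.9%), against 45.1% elsewhere (one-sided Fisher's exact p = 0.177), which neither excludes it nor speaks for it.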
